A study of Drosophila melanogaster with 4 samples.

How the data were processed

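H3K27ac ChIP-seq and matching input libraries were made from head nuclei of wild-type Oregon-R adults, with 2 ChIP and 2 input libraries. Per the labels' protocols, heads were separated with sieves, the tissue was crosslinked with formaldehyde, and chromatin was sheared by sonication before immunoprecipitation. Reads were mapped with Bowtie 0.12.7, per the submitters' processing notes. Positions refer to FlyBase release 5, per the file headers, which also give the length of every sequence; these lengths were used as denominators. The authors deposited 3 lists of enrichment clusters, 1 for each ChIP replicate, called with the input of the same number per the labels, and 1 for the replicate set. The cluster caller, its thresholds, and how the replicates were combined for the replicate-set list are not given in the sources used here. Each cluster carries a score in the authors' deposited lists, whose formula is likewise not given. The input libraries entered only through the authors' calls, and their own signal was not analysed here. Read depth is unknown, so a difference in depth between the libraries could change how many clusters were called and how wide they are; this was not tested.

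The log base of the scores was settled from the values. Differences from a reference score within each list (the commonest score of a replicate list, the highest of the replicate-set list) were raised to a base. With base 2 they gave ratios of whole numbers, with denominators up to 20000 and a relative tolerance of 1e-12, for 100% of clusters in replicate 1, 99.97% in replicate 2 and 91.9% in the replicate set. With base e the shares were 0.34%, 0.28% and 0.01%, and with base 10 they were 0.44%, 0.35% and 0.01%. A difference of 1 in score was therefore read as a doubling on the linear scale. What the ratio is taken over is not given in the sources used here, and no read counts were derived from it. Scores were used to describe and rank clusters within a list, to relate matched clusters, to compare their change between chromosomes in a comparison added later, and to rank regions by the mean over both replicates.

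The replicate-set list marks 1 region as depleted (3L from 11788126 to 11789793, 1668 bp, score -0.01); it was left out of all counts, and all other entries were used as deposited. Clusters overlapped when they shared at least 1 bp. Overlap between replicates was tested against 1000 circular shifts of replicate 2 within each sequence, which keep the widths and spacing of its clusters (one-sided). For the relation of scores, each cluster of replicate 1 was matched to the cluster of replicate 2 that shared most bases with it. Covered share, clusters per Mb and the ratio of the X to the 4 autosome arms (2L, 2R, 3L, 3R) were computed per replicate and are given as mean ± SD over both. Differences between the X and the autosome arms in covered share were tested by permuting blocks of 1 Mb 10000 times (two-sided); such tests compare positions within these libraries, not replicates. Intervals on shares are 95% Wilson intervals. Regions were named by a fixed rule: the 10 of highest mean score and the 10 widest among those in both replicate lists, and the 3 of highest score found in 1 replicate list alone, per replicate. Windows, cluster-free stretches and the highest replicate-set clusters were chosen after the values were seen.

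The groups, main tests, naming rule and most alternatives were chosen before the data were examined; those added later are named in the closing section. Alternatives were stricter overlaps, only clusters scoring or measuring at least the median of their list, merging of clusters within 500 bp, windows of 10 kb in place of bases, and leaving out each replicate. The planned comparisons with gene positions were not run, because a gene annotation of release 5 was not used here and coordinates were not converted between releases. The overlap test and the block test were tested on simulated data. With unrelated lists of the real size (5898 clusters) the overlap test called 0 of 20 runs, and with 60% of clusters kept in place it called 20 of 20. Over 117 blocks, the block test of the change on the X called 0 of 20 runs with no change and 20 of 20 with 1 percentage point added. The runs with unrelated lists or no change were made by the same shifts and shuffles that the tests use, so few calls follow from the setup. Shuffling also removes any relation between neighbouring blocks, so the rate of false calls under such a relation was not measured. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.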

Results

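Acetylation of histone H3 at lysine 27 (H3K27ac), a mark found at active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in nuclei from heads of adult fruit flies. The flies were of the wild-type laboratory strain Oregon-R and of mixed adult age, and the antibody came from Active Motif. There were 4 libraries, 2 from ChIP and 2 from input chromatin, and per the labels each input served as the background for the ChIP library of the same number. The measurements used here are the authors' lists of enrichment clusters, 1 list for each ChIP replicate and 1 for the replicate set, with positions on release 5 of the genome. Read depth per library is unknown, so intervals on shares of clusters cover counting error only. Nothing in the labels says whether the replicates came from separate fly collections, and the spread between them may therefore be technical.

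H3K27ac clusters in heads covered 27.6 Mb in replicate 1 and 28.1 Mb in replicate 2, which is 16.4% and 16.6% of the listed sequence. Replicate 1 held 5898 clusters with a median width of 3074.5 bp, and replicate 2 held 6056 with a median width of 3032.5 bp. Most clusters were a few kilobases wide, but a minority formed long domains. In replicate 1, 535 clusters (9.07%) reached 10 kb and together made up 31.4% of the covered sequence; in replicate 2, 531 clusters (8.77%) made up 30.8%. The widest cluster measured 64422 bp in replicate 1 and 57209 bp in replicate 2. Wider clusters had higher scores within each list, with Spearman's rho across clusters of 0.80 in replicate 1 and 0.79 in replicate 2. Neighbouring clusters are not independent of each other, so no p-value is attached to these relations. Median scores were 0.85 and 0.82, with ranges of 0.10 to 2.54 and 0.06 to 2.53.

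The region with the highest mean score over both replicates lay on 3R from 5901794 to 5928610, with a score of 2.52 ± 0.01 (SD, n = 2, as for all values given with ± here) and a width of 26.9 ± 0.11 kb. A region on 2R from 5428593 to 5449204 followed at 2.47 ± 0.10. Of the 10 highest-scoring regions, 6 lay on the X, 2 on 3R and 2 on 2R. On the X these were 3564785 to 3593718 (score 2.41 ± 0.03), 11706075 to 11718116 (2.32 ± 0.06), 6744631 to 6773269 (2.32 ± 0.04), 12608454 to 12664872 (2.29 ± 0.05), 17550577 to 17556740 (2.28 ± 0.10) and 7582688 to 7605627 (2.28 ± 0.08). The remaining regions were 3R from 5162789 to 5181257 (2.25 ± 0.07) and 2R from 16882813 to 16889918 (2.24 ± 0.08). These 10 regions were 6.41 to 57.5 kb wide, against a median of 3.39 kb for the 5166 regions matched between the replicates. Differences among scores from 2.24 to 2.32 are similar in size to the spread between replicates, so the order within that range is not resolved. The order above that range differed between replicates and is not resolved either. In replicate 1 the 2R region from 5428593 (score 2.54) lay above the 3R region from 5901794 (2.51). In replicate 2 the same 2R region scored below both that 3R region and the X region from 3564785.

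The widest domains were spread over the arms, with 3 on 2R, 3 on 3L, 2 on 3R, 1 on 2L and 1 on the X among the first 10. The domain on 2R from 6413088 to 6465875 had the largest mean width, 58.6 ± 8.23 kb, and replicate 1 held it as a single cluster where replicate 2 had a break. Its width of 52788 bp in replicate 2 was below those of domains on 2L (57209 bp), 2R from 14190393 (56549 bp), 3L from 10313334 (56443 bp), the X (56419 bp) and 3R from 12030023 (53667 bp). The order of the widest domains is therefore not resolved. On the X, the domain from 12608454 to 12664872 measured 57.5 ± 1.5 kb and was the only region among both the widest 10 and the highest-scoring 10. Next came 2R from 14190393 to 14246928 (56.7 ± 0.28 kb), 3L from 10313334 to 10369641 (56.4 ± 0.08 kb) and 3R from 12030023 to 12083656 (55.6 ± 2.77 kb). The other domains were 2L from 12470270 to 12511959 (49.4 ± 10.97 kb), 2R from 9888384 to 9926768 (43.2 ± 6.78 kb), 3L from 10217183 to 10254442 (38.9 ± 1.32 kb), 3L from 21871263 to 21908686 (37.9 ± 0.67 kb) and 3R from 5751947 to 5785764 (35.2 ± 1.76 kb). Their scores ranged from 1.27 to 2.29, against a median of 0.89 over all matched regions. Coordinates are those of the sequence shared by both replicates. Each width is that of 1 cluster per replicate, so pieces split off by a gap in the calls are not counted. On 2L the widths were 41690 bp in replicate 1 and 57209 bp in replicate 2. Which regions rank among the widest may thus depend on such gaps. Genes at these positions were not assigned, because an annotation of release 5 was not used here.

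**Figure D1:**
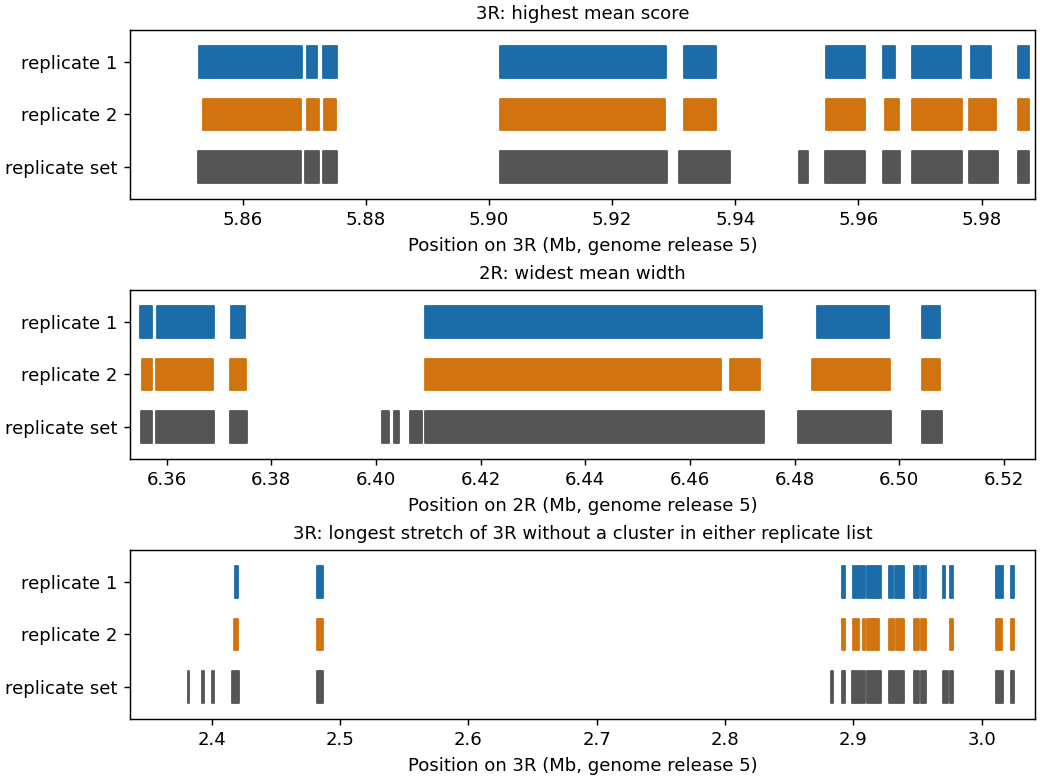
Bars show H3K27ac clusters of replicate 1, replicate 2 and the replicate set along 3 regions, with position in Mb of genome release 5 on the horizontal axis: the region of highest mean score (3R, score 2.52), the domain of largest mean width (2R, 58.6 kb) and the longest stretch of 3R with no cluster in either replicate list (405 kb). The cluster edges of the replicates nearly coincide at the first region, and replicate 2 has a break near the right end of the 2R domain.

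Both replicates placed H3K27ac at largely the same positions. Of the 5898 clusters of replicate 1, 5423 (91.9%, 95% Wilson interval 91.2 to 92.6) overlapped a cluster of replicate 2, and 5472 of 6056 (90.4%) did so in the other direction. The covered bases had a Jaccard index of 82.9%. Among the 4527 clusters matched 1 to 1, the median distance was 126 bp between starts and 131 bp between ends, and widths had a rho of 0.92. Shifting the clusters of replicate 2 by a random distance along each sequence gave an overlap of 37.7% ± 0.87 (SD over 1000 shifts) with a maximum of 48.5%, and a mean Jaccard index of 13.02%. The observed overlap exceeded every shift (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). That test shows shared positions in these libraries and does not separate biological from technical sharing.

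Clusters that scored high in 1 replicate also scored high in the other, with Spearman's rho of 0.89 and Pearson's r of 0.91 across 5423 matched clusters. By arm, rho was 0.89 on 2L, 0.89 on 2R, 0.91 on 3L, 0.88 on 3R and 0.84 on the X. Clusters are not independent replicates, so these are descriptions without a test.

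**Figure D2:**
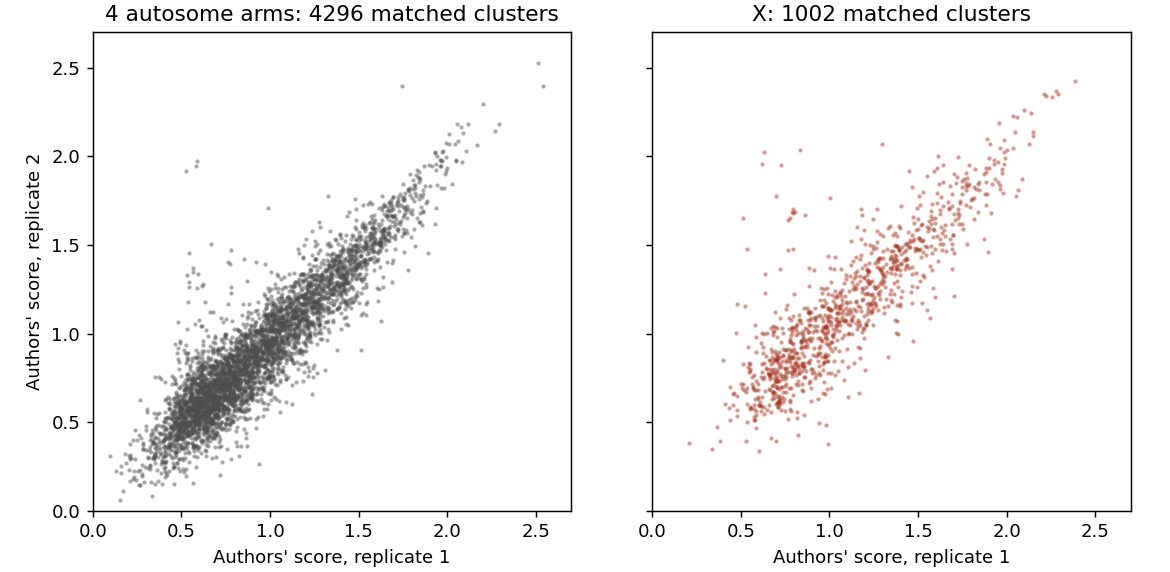
Each point is 1 matched cluster, with the authors' score in replicate 1 on the horizontal axis and in replicate 2 on the vertical axis, for the 4 autosome arms (4296 clusters, rho 0.89) and the X (1002 clusters, rho 0.84). Points follow a rising band in both panels, with a few far above it.

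Clusters found in 1 replicate alone were narrow and scored low. Replicate 1 had 475 of them (8.05%), with a median width of 1664 bp against 3294 bp for its shared clusters and a median score of 0.55 against 0.90. In replicate 2 there were 584 (9.64%), at 1685.5 bp against 3324 bp and 0.57 against 0.86. None reached 10 kb in either replicate, and 75.4% and 58.7% fell among the lowest 25% of their own list by score. The highest-scoring of them in replicate 1 were 2RHet from 341570 to 343020 (score 1.40), chromosome 4 from 1345949 to 1347453 (1.02) and 2L from 15670845 to 15672248 (1.01). Replicate 2 alone held 3R from 17127594 to 17129658 (1.93), 2L from 15677057 to 15678381 (1.32) and 3L from 23664707 to 23667597 (1.24). All 6 overlapped a cluster of the replicate-set list, as did 464 (97.7%) and 567 (97.1%) of the clusters found in replicate 1 or replicate 2 alone.

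H3K27ac clusters covered 20.2% ± 0.18 of 2L, 21.8% ± 0.20 of 3L, 22.5% ± 0.02 of 3R, 24.1% ± 0.12 of 2R and 26.6% ± 0.94 of the X. The small chromosome 4, which is largely heterochromatic yet carries active genes, had 22.1% ± 0.73 under clusters, close to the 22.1% ± 0.07 of the 4 autosome arms together. The separately assembled heterochromatin of the other chromosomes had far less. XHet was covered to 7.72% ± 0.47, 2LHet to 3.52% ± 0.14, 3LHet to 2.6% ± 0.05, 2RHet to 1.32% ± 0.14 and 3RHet to 0.86% ± 0.13. U, which holds unplaced sequence, was covered to 0.36% ± 0.06, and YHet (0.347 Mb) and Uextra (29.0 Mb) held no cluster in either replicate list. The gaps between the autosome arms exceeded the spread between replicates, that between 3L and 3R least clearly, and the X had the largest spread of the 5 major arms; no test was made over 2 replicates. Repeats limit how many reads can be placed in heterochromatin, and which reads the authors kept there is not given in the sources used here.

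**Figure D3:**
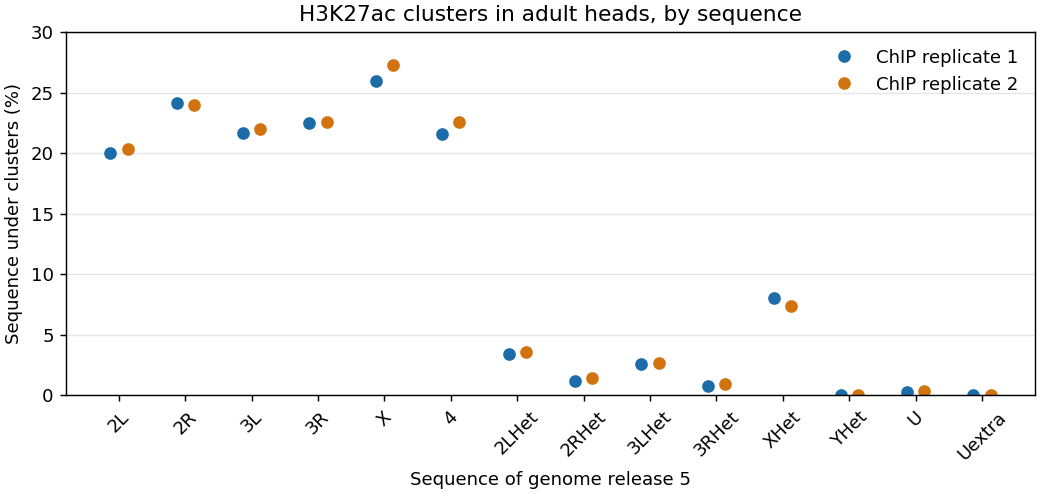
Points give the percentage of each sequence of genome release 5 under H3K27ac clusters in replicate 1 and replicate 2, shown separately. The X is highest in both (25.9% and 27.3%), chromosome 4 lies among the autosome arms, and the Het, U and Uextra sequences lie between 0 and 8.05%.

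Along most arms, clusters thinned out toward the centromere. The 2 Mb next to the centromere end were covered to 9.43% ± 0.17 on 2L, 10.8% ± 0.38 on 2R, 5.37% ± 0.14 on 3L and 10.4% ± 0.69 on the X, against 24.4% ± 0.01, 24.7% ± 0.49, 28.2% ± 0.53 and 29.2% ± 1.78 for the 2 Mb at the opposite end. 3R went the other way, with 28.3% ± 0.08 at its centromere end and 19.4% ± 0.26 at its telomere end. In full windows of 500 kb on the 5 major arms, the highest coverage was 52.5% ± 0.80 on 3R from 19500001 to 20000000, followed by 48.4% ± 0.89 on 3R from 5500001 to 6000000 and 45.3% ± 0.34 on the X from 6500001 to 7000000. The lowest mean among these full windows was 1.14% ± 0.0003 on 3L from 24000001 to 24500000. Its neighbour from 23500001 to 24000000 had 1.28% ± 0.41 and was the lower of the pair in replicate 1 (0.99% against 1.14%), so their order is not resolved. On the same arms, the median gap between neighbouring clusters of either replicate was 5076 bp, while 149 gaps reached 100 kb and 17 reached 200 kb. The longest stretch of these arms without a cluster in either replicate list was 461 kb on 3L, from 24068924 to 24529450. Next was 405 kb on 3R, from 2486514 to 2891324, and then 342 kb on the X, from 21502117 to 21844346. Of the 10 longest, 7 lay within 2 Mb and 9 within 3 Mb of the centromere end of their arm. A stretch of 254 kb on the X, from 14219733 to 14473921, was the exception.

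**Figure D4:**
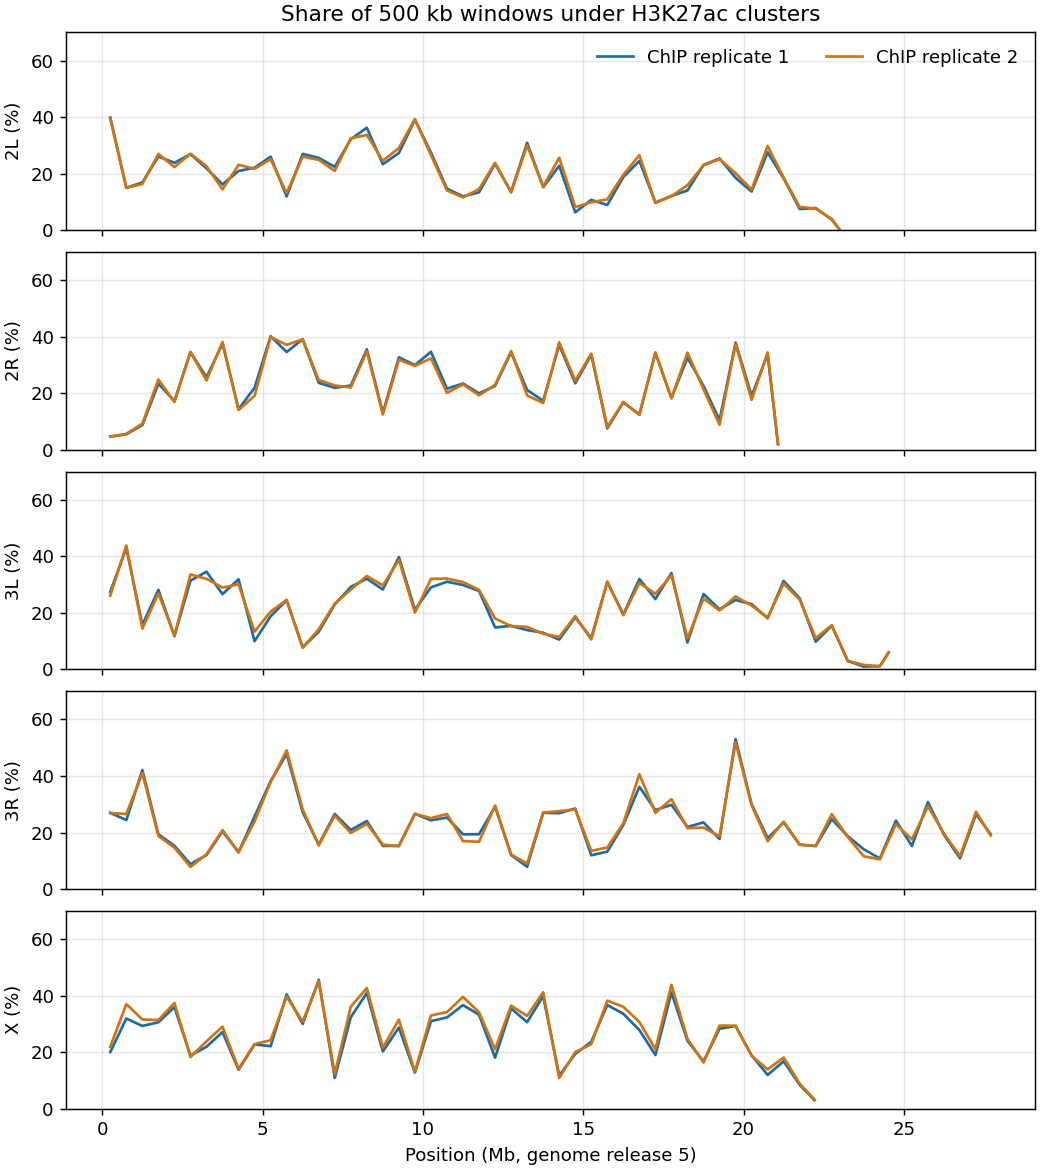
Lines show the percentage of consecutive 500 kb windows under H3K27ac clusters along the 5 major arms in replicate 1 and replicate 2, with position in Mb of genome release 5; the last window of an arm is shorter. The replicates nearly coincide, coverage falls at the centromere end of 2L, 3L and X (right) and 2R (left), and the highest window is on 3R at 52.5%.

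In fruit flies the single X of males is upregulated by dosage compensation, which makes the X against the autosomes the chromosome comparison that the species implies. The X had 1.17 times the covered share of the 4 autosome arms in replicate 1 and 1.23 times in replicate 2, a mean of 1.20 ± 0.04. Cluster density did not differ by more than the spread between replicates, at 49.7 ± 2.37 clusters per Mb on the X against 49.0 ± 0.55 on the autosome arms, a ratio of 1.01. Counted as 10 kb windows that hold a cluster, the X (52.3% ± 1.10) lay below 2R (54.4% ± 0.33) and chromosome 4 (56.2% ± 0.52), so its first rank holds for covered bases and not for windows. The clusters of the X were instead wider, with a median of 3379.5 ± 21.9 bp against 2996.75 ± 20.2 bp, and higher in score, with a median of 1.00 ± 0.01 against 0.79 ± 0.03. Within each list, the median score of the X lay above that of the autosome arms by 0.18 in replicate 1 and 0.24 in replicate 2, which on the linear scale is a factor of 1.13 and 1.18. Among the 100 highest-scoring clusters, 48 in replicate 1 and 50 in replicate 2 were on the X, which held 18.2% and 19.0% of all clusters. Chromosome 4 had a median score of 1.00 ± 0.01 at 67 clusters in each replicate, close to the X, with a median width of 3371 ± 110 bp. Its density of 49.6 clusters per Mb was also close to that of the X, yet it was covered to 22.1% ± 0.73 against 26.6% ± 0.94. The median width thus does not by itself account for the covered share of the X. The labels do not give the sex of the flies, so male and female contributions to the X cannot be separated here.

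The replicate-set list held 6949 enriched clusters over 34.0 Mb, more than either replicate list, with a median width of 3000 bp. Of these, 4841 (69.7%, 95% Wilson interval 68.6 to 70.7) overlapped clusters of both replicates and made up 89.1% of its covered sequence. A further 420 (6.04%) overlapped replicate 1 only, 502 (7.22%) overlapped replicate 2 only, and 1186 (17.1%, 16.2 to 18.0) overlapped neither. Those in neither list were narrow, with a median width of 1341.5 bp against 3611 bp for the rest, and scored lower, with a median of 0.39 against 0.73. They made up 5.11% of the covered sequence of the list. Nearly all replicate clusters overlapped the replicate-set list, 5887 of 5898 (99.8%) from replicate 1 and 6039 of 6056 (99.7%) from replicate 2. On the X the replicate-set list covered 33.3%, against 26.8% of the autosome arms, a ratio of 1.24. It is a single list, so its values carry no spread between replicates.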

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

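Tests added after the data were seen were the overlap on the major arms and without the lowest 10% of scores, the score relation on the major arms, the X ratio without 2 Mb at the centromere ends, for clusters in both lists and in 10 kb windows, all tests of the change in covered share on the X between replicates, and leaving out a replicate for the cluster count and the replicate-set list. The block test of the covered share of the X against the autosome arms was also added after the data were seen, though before its own result. The overlap between replicates stayed above its shifts under all 8 alternatives, at 83.6% to 92.4%. The score relation rose to a rho of 0.926 with 50% reciprocal overlap and 0.919 for clusters matched 1 to 1, which match fewer clusters (4933 and 4527). With 50% reciprocal overlap, 79.8% of the replicate-set clusters matched a replicate cluster in place of 82.9%. Restricting each list to scores at or above its median gave 86.9% for that share and 2989 clusters per replicate in place of 5977. It gave 16.9% of the major arms covered in place of 23.0%, and a ratio of the X to the autosome arms of 1.48 in place of 1.20. Fewer clusters enter each. The cut (0.85 in replicate 1, 0.82 in replicate 2) lay below the median score of the X (0.99 and 1.01) and above that of the autosome arms (0.82 and 0.77). It thus kept a larger part of the clusters of the X, and the rise in the X ratio goes with that. Why clusters of the X score higher was not tested. Counting 10 kb windows that hold a cluster gave 50.1% for the major arms, since a window counts whole. It also moved the X, highest by covered bases, below 2R and chromosome 4, with 52.3% of windows against 54.4% and 56.2%, and its ratio to the autosome arms fell to 1.05. Counting clusters per Mb brought the X ratio to 1.01. The X had 48.0 clusters per Mb against 48.6 on the autosome arms in replicate 1, and 51.3 against 49.4 in replicate 2. The excess in covered share thus lay mostly in the mean width per cluster, which is covered share divided by density. The X ratio was 1.17 to 1.23 when either replicate was left out, 1.24 in the replicate-set list, 1.23 without the centromere ends and 1.20 for clusters in both lists. With 1 replicate left out, the share of replicate-set clusters matched was 75.7% to 76.9%, since 1 list holds fewer clusters. Comparisons with gene positions were not run under any setting. No paired analysis was possible because the input libraries, which share the replicate numbers with the ChIP libraries, entered only through the authors' calls, and no test compared groups of libraries. Read depth is unknown and its effect was not tested. Among clusters scoring at or above the median of their own list the overlap was 90.3%, against 91.9% of all clusters. The shifts gave a mean of 29.9% for the former and 37.7% for the latter, and the cut also removes partners from the other list. These shares therefore cannot be compared directly and do not bear on depth.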

Other observations

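Chosen only after the result was seen were the 3 tests of the change in covered share on the X between replicates, both chromosome 4 comparisons, the score changes of matched clusters, and the choice of neighbouring regions and of the highest replicate-set clusters; the other tests were set before their results were seen. Several named regions lay close together. On 3R the widest-domain region from 5751947 to 5785764 (35.2 kb) was 116 kb from the region of highest mean score, from 5901794 to 5928610. Both fell in the second most covered 500 kb window (48.4%). On 3L the domains from 10217183 to 10254442 and from 10313334 to 10369641 were 58.9 kb apart. Clusters called in 1 replicate alone were close together on 2L, where that of replicate 1 (15670845 to 15672248) lay 4.81 kb from that of replicate 2 (15677057 to 15678381).

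The highest scores of the replicate-set list were at clusters that neither replicate list holds. The first 5 were 3RHet from 1720117 to 1721276 (score 3.61), U from 6329428 to 6330428 (3.03), X from 4683542 to 4684542 (2.88), and 3R from 7205026 to 7206026 and from 17130993 to 17131994 (2.51 each), all 1001 to 1160 bp wide. The last of these lay 1.33 kb from the cluster on 3R that replicate 2 alone held with a score of 1.93. On chromosome 4 the covered share was 21.6% in replicate 1 and 22.6% in replicate 2, a difference of 1.04 percentage points that lay within the range of windows of the same length on the autosome arms (-1.24 to 1.61). The scores of its 65 matched clusters gave another picture, with a median of 0.04 higher in replicate 2, above the range of -0.09 to 0.01 for runs of as many clusters on the autosome arms; whether chromosome 4 changed is thus left open.

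The X had more sequence under clusters in replicate 2 (27.3%) than in replicate 1 (25.9%), while the autosome arms differed little (22.2% and 22.1%). Clusters on the X numbered 1076 in replicate 1 and 1151 in replicate 2, against 4693 and 4768 on the autosome arms. Median width on the X was 3395 and 3364 bp, so the rise went with cluster number and not with median width. Of the clusters in 1 replicate alone, 74 in replicate 1 and 137 in replicate 2 lay on the X. More called sequence on every arm alike is argued against by the difference of 1.23 percentage points between the mean change of the X and of the autosome blocks, outside the permuted range of -0.47 to 0.49 (permutation p = 0.0001, the smallest that 10000 permutations can give); this measures the pattern against variation along the arms, with 1 library on each side. Within 5 bins of mean coverage the difference was 1.13 points, outside -0.46 to 0.46, so a change that grows with coverage also leaves it unexplained, and a few regions of the X do as well, since 21 of its 22 blocks (95.5%) lay above the autosome median. With blocks of 500 kb or 2 Mb it was 1.24 or 1.23 points, and for clusters in both lists 0.78. For clusters scoring at or above the median of their list it was 2.13. That cut was 0.85 in replicate 1 and 0.82 in replicate 2, while the median score of the X was 0.99 and 1.01. The 2.13 thus depends in part on the scores and is not separate support. In the scores of matched clusters, where the pattern was first seen, the X exceeded the autosome arms by a median change of 0.08 (permuted range -0.02 to 0.02). A difference between the inputs or in the sex of the collected flies may underlie it and was not tested, and no biological explanation was tested.

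The X also had a larger covered share than every autosome arm in both replicates, though not in counts of 10 kb windows, where 2R was higher (54.4% against 52.3%). For the 4 autosome arms pooled, variation along the arms alone is argued against by a difference of 4.64 percentage points over 1 Mb blocks. That difference lay outside the permuted range of -3.45 to 3.42 (permutation p = 0.0075), although neighbouring blocks are not fully independent. The X was not tested against each arm separately, and 2R came closest (24.1% against 26.6%). Whether variation along the arms accounts for the lead over every arm thus stays open. Low coverage of the 2 Mb next to the centromere, as the source of that lead, is argued against too. Without them the X still exceeded the highest autosome arm, by 1.92 points in replicate 1 and 3.52 in replicate 2. Those 2 Mb were low on the X as well, at 10.4%, so leaving them out also raised the X. Sequence farther from the centromere was kept, so its part was not measured. Since cluster density was alike (a ratio of 1.01), the larger covered share amounts to a larger mean width per cluster on the X. That follows by arithmetic from the same lists and is not a tested explanation. Mappability, base composition, input signal and sex were not tested and stay open.

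For the 1186 clusters of the replicate-set list that neither replicate list holds, a lower minimum width (1001 bp against 1301 bp) could account for some. By their width in that list, 537 (45.3%, 95% Wilson interval 42.5 to 48.1) were narrower than 1301 bp, which is less than 50%. But their median width of 1341.5 bp lay close to that limit, and edges of matched replicate clusters differed by a median of 126 and 131 bp. A region's width in a replicate call may thus differ from the width counted. Whether the minimum width accounts for most of the 1186 clusters is therefore not decided. Their median score of 0.39 lay below 0.49, the 25th percentile of the replicate-set clusters that overlap either replicate list. But the calling threshold is not given in the sources used here, so whether the 1186 clusters lie near it stays open. Not all scored low: 8 of them scored above 1.54, the 95th percentile of the replicate-set list; 7 of the 8 were narrower than any replicate cluster and 3 lay on U. What sets those apart was not tested, and no biological explanation was tested.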
